A study of Bos taurus with 18 samples.

How the data were processed

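Gene expression was measured in the epithelium that lines the rumen, the fermentation chamber of the cattle forestomach, of 18 Holstein bull calves. Each calf gave 1 sample, hybridised with a single Cy3 label to 1 NimbleGen bovine oligonucleotide array. Per the labels, the calves drank milk replacer alone to day 42 and from then on milk replacer with either orchard grass hay or a calf starter grain. There were 6 groups of 3 calves, namely milk alone at day 14 and at day 42, grain at days 56 and 70, and hay at days 56 and 70. The series text gives the age of the youngest group as 3 weeks where the sample labels give day 14, and day 14 is used here. The labels call day 42 weaning, although milk replacer was still fed afterwards, and "weaned" below means after that day. Tissue was kept in RNAlater, and RNA was extracted with TRIZOL and treated with DNase, per the labels' protocols.

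The deposited files hold probe intensity on a linear scale as read from the scanned images with NimbleScan 2.4.31, per the file headers. The array carries 86063 probes for 45255 target sequences, of which 40808 have 2 probes and 4447 have 1, with no mismatch probes. The authors also deposited a mean intensity per target with a text description of it, and values normalised by RMA on a linear intensity scale, per the submitters' processing notes. The version and settings of RMA, and the annotation release behind the descriptions, are not given in the sources used here. The series table of values was identical to the RMA files (largest difference 0), with column medians from 494.112 to 526.814. Its scale was therefore linear and uncentred, and it gave no result of its own. The median raw intensity per array ranged from 496.86 to 877.2. The number of arrays, 3 per group, limits the precision, and no read depth applies.

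From the probe intensities, background was corrected with limma's normexp method (offset 50), arrays were quantile normalised, and the probes of a target were summarised on the log2 scale by median polish with at most 20 iterations. These values correlated with the deposited RMA values at r = 0.9881 to 0.9886 per array, across targets, which are not independent. No pair of arrays held identical probe values (0 pairs). Across targets, r between 2 arrays had a median of 0.9655 within groups and 0.9551 between groups. Principal components 1, 2 and 3 held 27%, 22.6% and 13.9% of the variance. All targets were tested and none was filtered out.

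A single limma model with 1 mean per group was fitted to all 18 arrays (12 residual degrees of freedom), with empirical Bayes moderation. In it 10 contrasts were tested two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A target was called at an adjusted p under 0.05. Contrasts against milk at day 42 change age and diet together. All 3 calves of a group are separate animals, per the labels. R 4.3.3 with limma 3.58.1 and Python 3.11.15 were used.

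Names came from the deposited target descriptions. A description was present for 27561 targets, was usable for 20384 at a coverage of at least 10%, and named a protein for 17005, giving 12472 distinct named genes. Only 2131 targets could be given 1 gene symbol, 0 had several and 43124 had none. The rule for the genes named in the text had been written for targets with 1 symbol and was therefore widened to any target whose description names a vertebrate protein, a departure made before any result was seen. Left out were 14 protein names that over 9 targets share, with 870 targets. The descriptions can be old, and names are given as they stand there. The rule took targets past the threshold, at or above the median mean intensity of all targets (9.318 on the log2 scale), and without overlap between the calves on both sides. Of these it took up to 10 with the largest rise and 10 with the largest fall, using for each gene the target with the highest mean, and up to 4 members of each gene list by smallest p. Where none passed, it took the 3 with the smallest p each way. A gene named outside the rule is said to be so. Some genes that the rule took are not reported here.

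There were 32 gene lists of metabolism, transport, epithelial structure, immune function, growth, stress and cell types, and 567 of their 754 symbols were measured after 3 pairs of aliases were counted once. Each list was tested with limma's camera at a preset correlation of 0.01 against the 12472 named genes, with 1 target per gene. That background was chosen before any result was seen. Camera with an estimated correlation and limma's fry were run beside it, adjusted over the lists within a contrast. Camera asks whether a list moved relative to the other genes. Fry asks whether its genes moved on balance one way and does not compare them with other genes. Members called were counted after adjustment over all targets and also adjusted over the list alone. The groups, contrasts, lists, naming rule and the alternative settings, apart from those said below to be added, were fixed before the data were examined.

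The file headers placed the arrays in 3 processing days, A with 13 arrays, B with 4 (calf hay_day56_109 and calf hay_day70_101 on hay, calf milk_day14_108 of the day 14 group and calf milk_day42_114 of the day 42 group) and C with 1 (calf milk_day14_113 of the day 14 group). Results were recomputed with the processing day as a block and within a day. The other alternative settings were the authors' RMA values, no background correction, normexp with offset 0, median scaling, leaving out dim targets, fitting only the groups compared, an intensity trend with robust variance, array weights, other targets of a gene, the mean over the targets of a gene, and leaving out each calf in turn. Array weights by a gene-by-gene method, day A alone and a smooth muscle covariate were added after seeing the data.

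The fit was tested on simulated data with 200 changed targets per contrast among 45255. The changed targets were drawn from those at or above the median mean intensity. Errors were independent, with no processing day and no outlying calf. The shares below therefore do not cover dim targets or such effects. They may also be too low for contrasts in which far more than 200 targets change, where the adjustment of p-values is less strict. For the weaning contrast it found 54% of targets with a true log2 difference of 1 and 90% of those with 2, and 3.94% of calls were false. For grain at day 56 against milk at day 42 it found 12% and 84%, for diet over both ages 62% and 94%, and for diet at day 56 18% and 90%.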

Results

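Gene expression was measured in the rumen epithelium of 18 calves, 3 in each of 6 groups, to follow it from milk feeding through weaning on grain or on hay. The groups were milk alone at days 14 and 42, and grain or hay at days 56 and 70. Each array gave values for 45255 targets, its median raw intensity lay between 496.86 and 877.2, and the number of arrays limits the precision. Log2 differences are given with their standard error and limma's adjusted p-value, and group levels as mean ± SD of log2 intensity with n = 3.

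The question how expression changed when solid feed was added was asked first over all weaned calves, against day 42. SLC26A3, an intestinal chloride and bicarbonate exchanger, rose by 5.27 log2 units over the 4 weaned groups (SE 0.492, adjusted p = 2.04e-05). It went from 8.85 ± 1.28 in the day 42 group to 14.18 ± 0.498 on grain and 14.29 ± 0.325 on hay at day 56. Large rises were also found for UDP-glucuronosyltransferase 2B4, a detoxifying enzyme (4.82, SE 0.357, adjusted p = 2.81e-06), and alcohol dehydrogenase 6 (4.81, SE 0.831, adjusted p = 0.00204), whose day 42 level of 7.246 ± 0.0223 was dim. The sodium-dependent serotonin transporter rose by 3.12 (SE 0.232, adjusted p = 2.81e-06). Kynureninase, an enzyme of tryptophan breakdown, rose by 3.05 (SE 0.308, adjusted p = 3.38e-05), and very-long-chain acyl-CoA synthetase by 3.09 (SE 0.293, adjusted p = 2.18e-05). Metallothionein-1, a metal-binding protein, rose by 3.42 (adjusted p = 0.000184). Trichohyalin, a structural protein of keratinised cells, rose by 2.99 (adjusted p = 0.00122), and monoamine oxidase B by 3.30 (adjusted p = 0.000781). A further target of monoamine oxidase B went the other way (-0.62, adjusted p = 0.385), and dim further targets of metallothionein-1 and kynureninase did not pass (0.33 and 0.40, adjusted p = 0.17 and 0.0844). Of these rising genes, all but the serotonin transporter and trichohyalin had a day 42 mean below 9.318, the limit for dim targets, so the size and order of their rises are uncertain. KRT4, a keratin of non-cornified stratified epithelium, fell by 3.70 (SE 0.78, adjusted p = 0.00752), a lower bound as its day 42 level of 15.91 ± 0.0325 lay near the top of the scanner's range, and its other target fell by 4.66. Organic anion transporting polypeptide 3A1 fell by 2.16 (adjusted p = 8.58e-06), nephronectin by 1.98 (adjusted p = 3.28e-05), and the sodium- and chloride-dependent neutral and basic amino acid transporter B by 2.44 (adjusted p = 0.00312), with a dim further target at -0.38 (adjusted p = 0.406). Each gene named so far lay on the same side in all 12 weaned calves relative to all 3 calves of day 42, which the naming rule required.

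Most genes of ketone body formation, by which the rumen wall turns butyrate into ketones, rose in weaned calves. Of 6 measured members 4 rose and 1 fell (4 and 2 adjusted over the list alone). ACAT1 rose by 1.97 (SE 0.171, adjusted p = 1.18e-05) and BDH1 by 2.04 (SE 0.235, adjusted p = 0.000109). The member that fell was OXCT1, which uses ketones, from 11.89 ± 0.712 at day 42 to 10.34 ± 0.336 on hay at day 56; it was singled out after its values were seen. The list had a median of 1.13 (adjusted p = 0.0202, and adjusted p = 0.108 with an estimated correlation). In fatty acid oxidation 12 of 19 members rose and 1 fell (18 and 1 adjusted over the list alone), with HADH at 1.06, ACADS at 1.25 and the peroxisomal enzyme EHHADH at -1.25. Of 14 other PPAR targets 6 rose and 0 fell (6 and 0 adjusted over the list alone), among them the fatty acid carrier FABP4 (2.51, adjusted p = 0.000158) and the lipid droplet protein PLIN2 (1.34). In the TCA cycle 10 of 21 members rose (14 adjusted over the list alone), including MDH1 (0.98) and SDHD (0.75). In oxidative phosphorylation 23 of 46 rose (34 adjusted over the list alone), including the complex I subunits NDUFB5 (1.22) and NDUFC2 (1.21). The list medians were 0.802 for fatty acid oxidation (adjusted p = 1.59e-08), 0.473 for PPAR targets (adjusted p = 0.00149), 0.508 for the TCA cycle (adjusted p = 2.69e-06) and 0.575 for oxidative phosphorylation (adjusted p = 1.34e-12). With an estimated correlation the adjusted p was 0.062, 0.0778, 0.138 and 0.108 in that order.

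**Figure D1:**
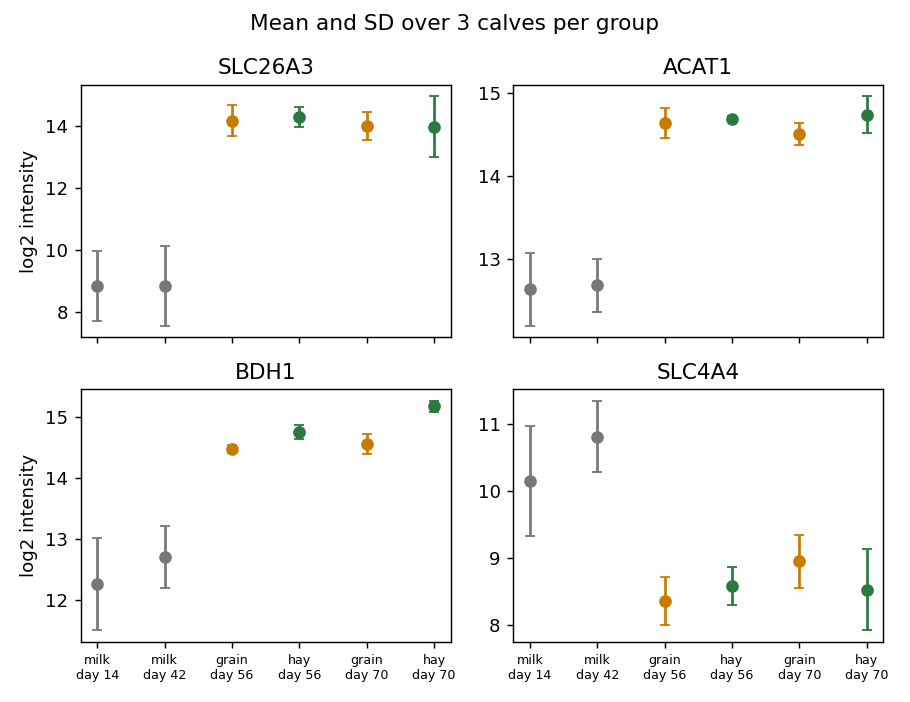
Log2 intensity (vertical axis) of 3 genes that rose and 1 that fell after day 42, in the 6 groups of diet and age (horizontal axis), with points for the mean and bars for the SD of 3 calves. SLC26A3 lay at 8.86 and 8.85 in the milk groups and between 13.98 and 14.29 in the weaned groups, while SLC4A4 was at 10.81 at day 42 and 8.36 on grain at day 56.

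Cell cycle genes were also higher in weaned calves, with 16 of 32 members called (22 adjusted over the list alone), among them CENPA of the centromere (1.41, adjusted p = 0.0019), the mitotic kinase AURKA (1.19) and NUSAP1 (1.10). Of 24 genes of oxidative stress and glutathione 11 rose (14 adjusted over the list alone), led by the detoxifying enzymes NQO1 (2.17, adjusted p = 0.000832) and GSTM1 (1.82, adjusted p = 0.000434). In the proteasome 4 of 29 rose (12 adjusted over the list alone), including PSMA3 (0.69, with another target at -0.08). Of 16 cytokines and chemokines 3 rose (3 adjusted over the list alone), namely IL18 (1.00), CCL5 (0.57, with another target at -0.03) and IL1A (1.39). The medians were 0.731 for the cell cycle (adjusted p = 1.42e-07), 0.712 for oxidative stress (adjusted p = 1.18e-05), 0.312 for the proteasome (adjusted p = 0.00149) and 0.387 for cytokines (adjusted p = 0.0478). The adjusted p with an estimated correlation was 0.447, 0.0778, 0.561 and 0.561 in that order. None of 12 smooth muscle markers was called (0 in limma over all targets and 2 lower adjusted over the list alone), and their median was -1.06 (adjusted p = 0.000404, and adjusted p = 0.561 with an estimated correlation). With the processing day as a block and within day A this median was -0.894 and -0.0238, and calf milk_day42_114 of the day 42 group carried high levels of these markers, as described with the milk groups.

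The remaining lists did not pass as lists, but several members did. Of 26 genes of short-chain fatty acid, acid-base and ion transport 3 rose and 3 fell (5 and 4 adjusted over the list alone, list adjusted p = 0.779), with the bicarbonate cotransporter SLC4A4 at -2.21 (adjusted p = 0.000473) and the proton exchanger SLC9A2 at 1.07. Keratinocyte differentiation had 2 higher and 2 lower of 17 (2 and 2 adjusted over the list alone, adjusted p = 0.926), with CSTB and TGM5 up by 1.08 and 1.35 and the desmosomal DSG1 down (-1.35). Among growth factors AREG rose by 2.08 and IGF2 fell by 0.93. Further targets of IGF2 lay at -0.71, -0.99 and -1.34, and a dim one at 0.12. Of this list 3 of 19 rose and 3 fell (3 and 5 adjusted over the list alone, adjusted p = 0.0538). BMP7 (-1.58) and BMP4 (-0.63) were the 2 of 22 TGF-beta genes that fell over all targets (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.0509). In tight and gap junctions 2 of 18 rose (3 adjusted over the list alone, adjusted p = 0.403), with CLDN4 at 1.23. The antimicrobial S100A7 fell by 2.28, the only call among 17 of its list in either count (adjusted p = 0.413). KRT14 (0.81) was the only call among 12 basal keratinocyte genes in either count (adjusted p = 0.988). The T cell receptor subunit CD3D rose by 1.51 (adjusted p = 2.04e-05), the single call among 12 T and NK markers in either count (adjusted p = 0.779). TUBB3 rose by 1.85 (adjusted p = 0.000142) among 9 nerve and glia markers (1 called, 2 adjusted over the list alone, adjusted p = 0.926). CXCR2 fell by 1.14 and HDC rose by 1.00 among 7 mast cell and granulocyte markers (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.591).

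Cholesterol synthesis had 1 higher and 1 lower of 20 in both counts (adjusted p = 0.838), with IDI1 at 0.58. Fatty acid synthesis had ACSS2 (0.98) and ME1 (0.71) up of 10 in both counts (adjusted p = 0.86), and glycolysis had 3 of 17 up (5 adjusted over the list alone, adjusted p = 0.118), with LDHA at 0.49. HSPE1 (0.60) of 20 heat shock genes and IER3 (1.04) of 14 immediate early genes were the only calls in either count (adjusted p = 0.926 and 0.978). COL6A1 (-1.49) was the only call among 23 fibroblast genes in either count (adjusted p = 0.207). The adjusted p was 0.789 for interferon response, 0.403 for ribosomal proteins, 0.7 for endothelial, 0.88 for B and plasma cell, 0.932 for macrophage and 0.757 for red blood cell markers, with 0 members called by limma in either count. Mean and median differed in sign for keratinocyte differentiation (-0.0593 and 0.267), cholesterol synthesis (-0.0208 and 0.00542), heat shock (0.0817 and -0.0207), interferon response (0.00119 and -0.103) and nerve and glia (0.0888 and -0.166). The test pointed down for the keratinocyte, cholesterol, interferon and nerve lists, and up for heat shock and for basal keratinocyte genes, whose median was -0.018.

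In all, 4220 of 45255 targets were called in this contrast, 2567 higher and 1653 lower, and 1469 of them by more than 2-fold. The calves did not overlap for 7.15% of all targets. With the processing day as a block 5722 targets were called, within day A 2740 and with the smooth muscle score as a covariate 2457. The medians with the block and within day A were 1.12 and 1.06 for ketone body genes, 0.81 and 0.75 for fatty acid oxidation and 0.476 and 0.75 for PPAR targets. They were 0.489 and 0.393 for the TCA cycle and 0.609 and 0.583 for oxidative phosphorylation. They were 0.748 and 0.601 for the cell cycle, 0.703 and 0.57 for oxidative stress, 0.3 and 0.309 for the proteasome and 0.355 and 0.351 for cytokines. Without calf milk_day42_117 of the day 42 group 1295 targets were called and without calf milk_day42_114 2179. The calls of KRT4 and of a target described as gene NMB protein, which fell by 1.98, were lost without calf milk_day42_117 (adjusted p = 0.0527 and 0.176), with ranges over the alternatives of 0.000212 to 0.0527 and 0.00444 to 0.176. The call of the latter was also lost without calf milk_day42_114, within day A and with the smooth muscle covariate. The cytokine list was lost with the block and within day A, and the smooth muscle list within day A. Further targets of ACADS, NUSAP1, CSTB, COL6A1 and LDHA did not pass (0.54, 0.47, 0.37, -0.45 and 0.33). Median scaling in place of quantile normalisation moved the share of higher calls from 60.8% to 73%, with a shift of up to 0.108 in the median of all targets of a group.

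During the first 2 weeks on grain SLC26A3 rose by 5.33 (SE 0.622, adjusted p = 0.000381) and alcohol dehydrogenase 6 by 5.11 (SE 1.05, adjusted p = 0.0151). The serotonin transporter rose by 2.85 (SE 0.294, adjusted p = 0.000184) and an intermediate-conductance calcium-activated potassium channel, from a dim 7.586, by 2.82 (SE 0.416, adjusted p = 0.00219). Monoamine oxidase B rose by 3.58 with another target at -0.89, and the neutral and basic amino acid transporter B fell by 3.04 (adjusted p = 0.00877), with a dim further target at -0.63 that did not pass. Of 6 ketone body genes 4 rose, with ACAT1 at 1.96 and BDH1 at 1.78, and 1 fell (4 and 1 adjusted over the list alone). In fatty acid oxidation 4 of 19 rose and 1, EHHADH (-1.16), fell (16 and 1 adjusted over the list alone). Of the PPAR targets 4 of 14 rose (6 adjusted over the list alone), with FABP4 at 2.61. In the cell cycle 10 of 32 rose (21 adjusted over the list alone), with CENPA at 1.72, AURKA at 1.41 and TOP2A, which untangles DNA, at 1.28. Oxidative stress had 8 of 24 higher (12 adjusted over the list alone), with NQO1 at 2.09. Oxidative phosphorylation had 7 of 46 higher (24 adjusted over the list alone) and the TCA cycle had 4 of 21 (10 adjusted over the list alone). Glycolysis had ALDOC (1.10) as 1 of 17 (3 adjusted over the list alone). Cytokines had IL18 (1.48) and CCL5 (0.72, with another target at -0.06) as 2 of 16 (3 adjusted over the list alone), and the proteasome PSMA3 (0.74, with another target at 0.10) as 1 of 29 in both counts. CD3D (1.87) and TUBB3 (2.39) rose, and IGF2 (-1.16) and SLC4A4 (-2.46) fell.

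The grain medians were 1.09 for ketone body genes (adjusted p = 0.015), 0.763 for fatty acid oxidation (adjusted p = 2.19e-07) and 0.356 for PPAR targets (adjusted p = 0.00274). They were 0.506 for the TCA cycle (adjusted p = 1.17e-05), 0.593 for oxidative phosphorylation (adjusted p = 1.2e-10) and 0.659 for oxidative stress (adjusted p = 7.07e-05). An estimated correlation gave adjusted p = 0.1, 0.1, 0.1, 0.177, 0.138 and 0.1 in that order. Further grain medians were 0.839 for the cell cycle (adjusted p = 1.06e-09), 0.292 for glycolysis (adjusted p = 0.0465), 0.445 for cytokines (adjusted p = 0.034), 0.321 for the proteasome (adjusted p = 0.00684) and -0.855 for smooth muscle markers (adjusted p = 0.00684), of which 0 were called by limma in either count. With an estimated correlation the adjusted p was 0.332, 0.716, 0.676, 0.716 and 0.716 in that order. With the processing day as a block and within day A, the median was 1.08 and 1.01 for ketone body genes, 0.731 and 0.655 for fatty acid oxidation and 0.361 and 0.751 for PPAR targets. It was 0.489 and 0.431 for the TCA cycle, 0.637 and 0.561 for oxidative phosphorylation, and 0.638 and 0.536 for oxidative stress. It was 0.886 and 0.808 for the cell cycle, 0.255 and 0.306 for glycolysis, 0.435 and 0.349 for cytokines and 0.33 and 0.333 for the proteasome. It was -0.519 and 0.127 for smooth muscle markers, so the muscle value turned within day A. Of the calves in this contrast, day A lacks only calf milk_day42_114. Its medians are therefore those without that calf, and day A cannot tell the processing day from that calf here. In total 1571 targets were called, 1109 higher and 462 lower, against 2168 with the block, 1266 within day A and 1027 with the smooth muscle covariate. The calves did not overlap for 28.9% of all targets where chance gives 10%. The count was 444 without calf grain_day56_105, 648 without calf grain_day56_110, 689 without calf grain_day56_116, 378 without calf milk_day42_117 and 824 without calf milk_day42_114. The call of alcohol dehydrogenase 6 was lost without calf grain_day56_105 or milk_day42_117 and within day A, where its adjusted p ranged from 0.000737 to 0.0762 over the alternatives. The lists of glycolysis and cytokines were lost with the block and within day A, that of smooth muscle with the block, and that of the proteasome within day A.

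During the first 2 weeks on hay UDP-glucuronosyltransferase 2B4 rose by 5.47 (SE 0.452, adjusted p = 3.29e-05) and alcohol dehydrogenase 6 by 5.61 (SE 1.05, adjusted p = 0.00409). SLC26A3 rose by 5.44 (SE 0.622, adjusted p = 0.000251), and phosphoenolpyruvate carboxykinase 2, an enzyme of glucose formation, rose from a dim 8.399 by 2.92 (SE 0.346, adjusted p = 0.000273). Testican fell by 2.91 (SE 0.447, adjusted p = 0.00121), and the actin-binding proteins scinderin and supervillin by 2.57 and 2.24 (adjusted p = 0.00987 and 9.47e-05). The Sda beta-1,4-GalNAc transferase, which adds a terminal sugar to glycans, fell by 4.22 (SE 1.19, adjusted p = 0.0372). In oxidative phosphorylation 29 of 46 members rose (36 adjusted over the list alone), with NDUFC2 at 1.91, NDUFB5 at 1.73 and NDUFB6 at 1.54. In fatty acid oxidation 11 of 19 rose, with ETFB at 1.39, and 1, EHHADH (-1.48), fell (17 and 1 adjusted over the list alone). Of 6 ketone body genes 4 rose, with BDH1 at 2.06, and 1 fell (4 and 2 adjusted over the list alone). Of 14 PPAR targets 5 rose (6 adjusted over the list alone), with ACOT1 at 2.84 and another target of it at 0.39 (adjusted p = 0.476), and of 21 TCA cycle genes 9 rose (12 adjusted over the list alone), with MDH1 at 1.23. Oxidative stress had 11 of 24 higher (15 adjusted over the list alone), with NQO1 at 2.44 and GPX1 at 1.86, of which another target lay at -0.67. The cell cycle had 10 of 32 higher (12 adjusted over the list alone), with AURKA at 1.21, and the proteasome 7 of 29 (17 adjusted over the list alone), with PSMA3 at 1.07 and another target of it at -0.002422. Ribosomal proteins had 3 of 36 higher (9 higher and 1 lower adjusted over the list alone), with RPLP2 at 1.07 and 2 further targets of it at -0.33 and -0.11. AREG (2.64) and CLDN4 (1.66) rose, and DSG1 (-1.82), COL6A1 (-2.02, with another target at -0.66) and SLC4A4 (-2.24) fell.

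The hay medians were 1.21 for ketone body genes (adjusted p = 0.0448), 0.961 for fatty acid oxidation (adjusted p = 3.01e-07) and 0.504 for PPAR targets (adjusted p = 0.00388). They were 0.567 for the TCA cycle (adjusted p = 1.59e-05) and 0.893 for oxidative phosphorylation (adjusted p = 4.05e-16). The adjusted p with an estimated correlation was 0.173, 0.065, 0.0823, 0.218 and 0.0823 in that order. Further hay medians were 0.583 for the cell cycle (adjusted p = 0.000334), 0.812 for oxidative stress (adjusted p = 1.74e-06), 0.344 for ribosomal proteins (adjusted p = 0.00388), 0.52 for the proteasome (adjusted p = 0.000235) and -0.957 for smooth muscle markers (adjusted p = 0.00215, with 0 called by limma in either count). An estimated correlation gave adjusted p = 0.662, 0.065, 0.267, 0.474 and 0.644 in that order. The processing day as a block could not move these medians, because both groups had the same number of arrays on each day. Within days A and B they were 1.15 and 1.33 for ketone body genes, 0.944 and 0.996 for fatty acid oxidation and 0.728 and 0.48 for PPAR targets. They were 0.401 and 0.7 for the TCA cycle, and 0.752 and 1.14 for oxidative phosphorylation. Within the same days they were 0.349 and 1.14 for the cell cycle, 0.768 and 1.01 for oxidative stress, 0.396 and 0.398 for ribosomal proteins and 0.455 and 0.553 for the proteasome. They were -0.175 and -3.22 for smooth muscle markers, where day B sets calf hay_day56_109 against calf milk_day42_114 alone. Of 4040 called targets (2664 higher and 1376 lower, 2195 by more than 2-fold), 4040 kept their sign within day A and 4037 within day B, on the same arrays that called them. Over all targets, which are not independent, the changes of days A and B correlated at r = 0.458. With the block 5922 targets were called and within day A 1824, and the calves did not overlap for 27.9% of all targets where chance gives 10%. The count was 1706 without calf hay_day56_109, 2404 without calf hay_day56_115, 1585 without calf milk_day42_117 and 2003 with only these groups in the fit. Median scaling moved the share of higher calls from 65.9% to 79.1%. The lists of ketone body genes, the cell cycle and smooth muscle were lost within day A. The transferase was lost without any 1 of the 6 calves (adjusted p up to 0.129, with alternatives from 0.00739 to 0.129).

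Grain and hay were compared with the same 3 day 42 calves, so part of their likeness comes from those shared controls. Across targets the log2 changes on both diets correlated at r = 0.857, within the range of -0.241 to 0.897 (mean 0.471) of simulated unchanged groups, and targets are not independent replicates. The same sign was found for 80.8% of targets, also within the simulated range of 38.2% to 87.3% (mean 66.4%). The covariance was 0.246 against a simulated mean of 0.0552, a difference of 0.191, and above the highest simulated value of 0.171. Both diets called 911 targets higher, where independent lists of those lengths share 65.3, and 399 lower, where they share 14, with 0 called in opposite directions. The 3 controls could not be split into 2 sets of at least 2 calves, so part of the excess may come from the shared controls.

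Between day 14 and day 42 on milk, no single gene passed the test, and the gene list with the lowest p was the smooth muscle markers. The contractile genes CNN1, MYH11, TAGLN and MYL9 had day 42 minus day 14 differences of -3.34, -2.86, -2.06 and -1.46 (adjusted p = 0.454 each). Of 12 smooth muscle markers 0 were called and 10 were lower adjusted over the list alone (median -1.79, adjusted p = 2.43e-07, and adjusted p = 0.564 with an estimated correlation). Their mean per calf was 13.14 to 13.5 in the day 14 calves and 13.59 in calf milk_day42_114 of the day 42 group, against 10.11 to 10.85 in the 14 other calves. Medians were -0.359 for oxidative phosphorylation (adjusted p = 2.93e-05), -0.296 for the proteasome (adjusted p = 3.18e-05) and -0.429 for fibroblast genes (adjusted p = 0.000793). They were -0.475 for S100 and antimicrobial genes (adjusted p = 0.0333), -0.273 for glycolysis (adjusted p = 0.0371) and -0.537 for interferon response (adjusted p = 0.038), each with 0 members called. With an estimated correlation the adjusted p was 0.564, 0.564, 0.729, 0.625, 0.729 and 0.74 in that order. Members by smallest p included NDUFB5 (-0.84), PSMC3 (-0.71), the elastic fibre genes MFAP4 (-0.98) and ELN (-1.01), and the interferon-induced MX1 (-1.31) and ISG15 (-1.14). Glycogen phosphorylase of the brain form (-1.41) and tissue-type plasminogen activator (-0.88) were among the genes with the smallest p (adjusted p = 0.454).

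**Figure D2:**
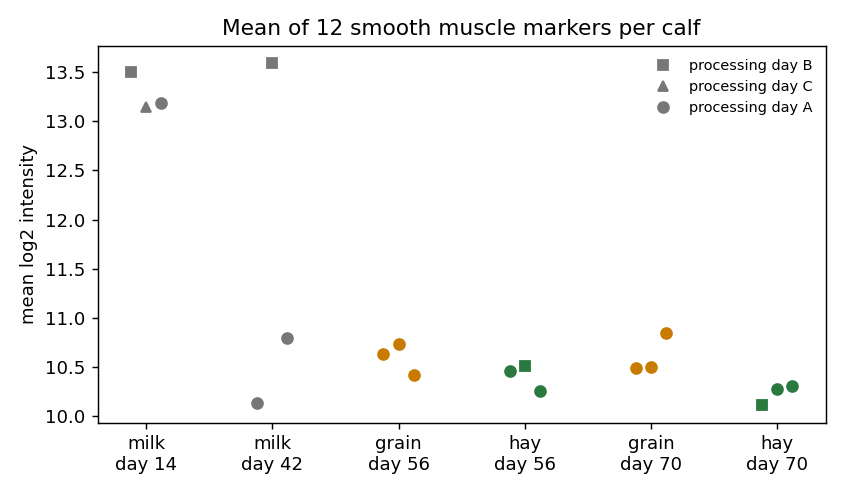
Mean log2 intensity of 12 smooth muscle markers (vertical axis) in each calf, by group (horizontal axis), with symbols for the processing day. The 3 day 14 calves and calf milk_day42_114 of the day 42 group lay between 13.14 and 13.59, and the 14 other calves between 10.11 and 10.85.

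In limma 0 of 45255 targets were called for age on milk, 4144 had an unadjusted p under 0.05, and the calves did not overlap for 8.73% of targets where chance gives 10%. With the processing day as a block 11 were called, and within day A 525, of which 515 were lower. Day A holds 1 day 14 calf, which is assumed to vary like the other groups in that fit. With the block, within day A and within day B the median was -1.67, -2.76 and 0.168 for smooth muscle and -0.565, -1.1 and 0.3 for fibroblast genes. It was -0.865, -1.92 and 0.0993 for interferon response and -0.365, -0.113 and -0.624 for oxidative phosphorylation. It was -0.299, -0.222 and -0.344 for the proteasome. It was -0.337, -0.352 and -0.426 for S100 genes and -0.0968, -0.0572 and -0.196 for glycolysis. Day B holds calf milk_day42_114 and day 14 calf milk_day14_108 alone, and the muscle, fibroblast and interferon medians turned there. The glycolysis and S100 lists were lost with the block and within day A, and the oxidative phosphorylation and proteasome lists within day A. The count was 609 without calf milk_day42_114 (562 lower), 7 without calf milk_day14_113 and 5 without calf milk_day14_108, and the interferon median turned to 0.12 without calf milk_day14_118.

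Whether the kind of feed mattered was asked by comparing grain with hay, which differed in few single genes when both ages were averaged. MMP-3, a matrix-degrading protease, was higher on grain by 2.14 (SE 0.285, adjusted p = 0.03) and a target described as BP40 precursor by 1.59 (SE 0.218, adjusted p = 0.03). The unnamed targets BOVINE0001S00041059 and BOVINE0001S00046461 differed by 1.75 (adjusted p = 0.0438) and -1.54 (adjusted p = 0.03). All 4 were dim, outside the naming rule and chosen after their values were seen. The xenobiotic-metabolising enzymes CYP1A1 and CYP1B1, targets of the aryl hydrocarbon receptor, had grain minus hay differences of -1.95 (SE 0.359, adjusted p = 0.114) and -1.63 (SE 0.292, adjusted p = 0.11), not past the threshold. With the block and within day A they were -1.98 and -2.19 for CYP1A1 and -1.55 and -1.69 for CYP1B1, and a dim further target of CYP1A1 lay at 0.27. MHC OVAR-DQ-alpha (1.27, adjusted p = 0.11), CD3D (0.68, adjusted p = 0.114) and TUBB3 (1.06, adjusted p = 0.114) did not pass.

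**Figure D3:**
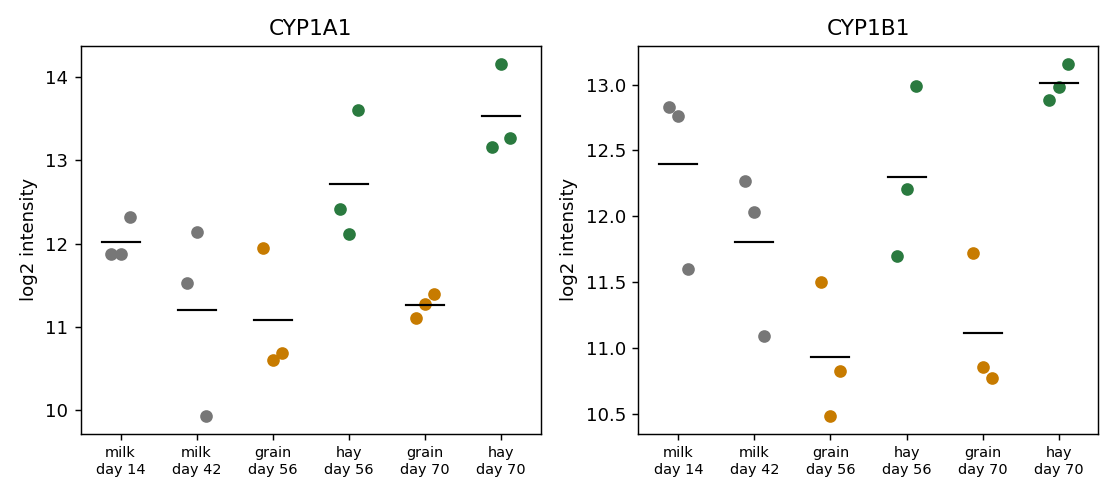
Log2 intensity (vertical axes) of CYP1A1 and CYP1B1 in each calf, by group (horizontal axes), with points for calves and lines for group means. CYP1A1 means were 12.71 and 13.53 on hay and 11.08 and 11.26 on grain at days 56 and 70, with no overlap between the diets, while CYP1B1 overlapped in 1 pair of calves (11.72 on grain and 11.7 on hay).

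The lists below lay higher or lower on grain as lists, with 0 members called by limma over all targets in each. Macrophage and dendritic markers had a median of 0.318 (adjusted p = 9.77e-06, 2 higher adjusted over the list alone), with the phagocyte oxidase subunit CYBB at 0.85. S100 and antimicrobial genes had 0.333 (adjusted p = 1e-04, 6 higher adjusted over the list alone), with PI3 at 1.46 and S100A9 at 1.78. Cytokines had 0.194 (adjusted p = 0.000875, 2 higher adjusted over the list alone), with CCL20 at 1.15 and IL1B at 0.62. The adjusted p with an estimated correlation was 0.457 for each. The cell cycle had a median of 0.308 (adjusted p = 2.74e-06), keratinocyte differentiation 0.177 (adjusted p = 0.00423, 1 higher adjusted over the list alone) and fibroblast genes 0.209 (adjusted p = 0.00261). T and NK markers had 0.179 (adjusted p = 0.0126, 1 higher adjusted over the list alone) and glycolysis 0.124 (adjusted p = 0.0166). An estimated correlation gave adjusted p = 0.522, 0.457, 0.66, 0.466 and 0.637 in that order. Lower on grain were oxidative phosphorylation (-0.0983, adjusted p = 0.00259), ribosomal proteins (-0.0998, adjusted p = 0.00628), fatty acid oxidation (-0.123, adjusted p = 0.0166) and oxidative stress (-0.0242, adjusted p = 0.0369, 2 lower adjusted over the list alone). With an estimated correlation the adjusted p was 0.637, 0.466, 0.466 and 0.489 in that order. Smooth muscle markers, of another tissue, had a median of 0.328 (adjusted p = 0.103) and 0.676 with the block. With the block and within day A the medians were 0.259 and 0.185 for macrophage markers, 0.297 and 0.154 for S100 genes, 0.159 and 0.0975 for cytokines and 0.265 and 0.307 for the cell cycle. They were 0.158 and 0.167 for keratinocyte differentiation, 0.261 and 0.113 for fibroblast genes, 0.0906 and 0.0638 for T and NK markers and 0.127 and 0.14 for glycolysis. They were -0.0867 and -0.0896 for oxidative phosphorylation, -0.0964 and -0.126 for ribosomal proteins, -0.142 and -0.11 for fatty acid oxidation and -0.0391 and -0.0368 for oxidative stress, which lay at 0.0185 without calf grain_day70_107. The oxidative stress list was lost with the block and within day A, and the T and NK list within day A.

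In total 4 targets were called between diets, 3 higher and 1 lower, with 2342 at an unadjusted p under 0.05, 0 called with the processing day as a block and 4 within day A, of which 0 were among the 4 of the full fit. The count was 15 without calf hay_day70_111, 10 without calf grain_day56_105, 2 without calf hay_day70_101, hay_day56_104, hay_day70_106 or grain_day70_107, 1 without calf grain_day56_116 and 0 without calf grain_day56_110, grain_day70_112 or hay_day56_115.

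At day 56, 14 days after the change of diet, oxidative phosphorylation genes lay lower on grain than on hay (median -0.323, adjusted p = 5.38e-10), with the complex I subunit NDUFB6 at -0.73, as did ribosomal proteins (-0.202, adjusted p = 2.05e-05), with RPL13 at -0.59. The adjusted p with an estimated correlation was 0.472 and 0.361. The cell cycle median was 0.224 (adjusted p = 0.00115), with CENPE at 0.75, the fibroblast median 0.154 (adjusted p = 0.0238), the proteasome median -0.142 (adjusted p = 0.0136) and the oxidative stress median -0.0972 (adjusted p = 0.0168). An estimated correlation gave adjusted p = 0.791, 0.791, 0.791 and 0.691 in that order, and limma called 0 members in any of the 6 lists in either count. With the block and within day A the medians were -0.299 and -0.28 for oxidative phosphorylation, -0.193 and -0.204 for ribosomal proteins and 0.239 and 0.325 for the cell cycle. They were 0.206 and 0.11 for fibroblast genes, -0.159 and -0.107 for the proteasome and -0.127 and -0.0889 for oxidative stress. The oxidative stress, proteasome and fibroblast lists were lost within day A, and the cell cycle median turned to -0.106 without calf hay_day56_115. Of the calves in this contrast, day A lacks only calf hay_day56_109, so its medians are those without that calf. Among single genes the GABA-B1a receptor (1.08), gamma adducin (0.85), an MHC class I protein (1.33, with another target at -0.29) and E2F-5 (-0.85) had the smallest p and did not pass (adjusted p = 1). The unnamed target BOVINE0001S00046461 was the only call (-2.52, SE 0.281, adjusted p = 0.00656), lower in 3 of 3 calves on grain. It was dim and chosen after its values were seen. In all 1711 targets had an unadjusted p under 0.05, and 14% of all targets had no overlap where chance gives 10%. With the block the same target alone was called, and within day A 2 others. The count was 0 without calf grain_day56_105 or grain_day56_110 and 2 without calf hay_day56_109 or grain_day56_116.

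At day 70 the S100, macrophage and cytokine lists had larger medians than over both ages. S100 and antimicrobial genes had a median of 0.69 (adjusted p = 7.78e-07, 5 higher adjusted over the list alone), with the neutrophil-associated S100A9 at 2.36 and PI3 at 1.65, and macrophage markers had 0.484 (adjusted p = 4.97e-07). Cytokines had 0.376 (adjusted p = 9.54e-05, 2 higher adjusted over the list alone), with CCL20 at 1.88 and IL1B at 0.98. Keratinocyte differentiation had 0.336 (adjusted p = 0.000183), with KRT4 at 3.27. With an estimated correlation the adjusted p was 0.277 for each. Glycolysis had 0.191 (adjusted p = 0.00145), with HK2 at 1.25, and T and NK markers 0.244 (adjusted p = 0.00256, 1 higher adjusted over the list alone). The cell cycle had 0.304 (adjusted p = 7.17e-05), the proteasome 0.184 (adjusted p = 0.00872) and fibroblast genes 0.235 (adjusted p = 0.0338). The adjusted p with an estimated correlation was 0.563, 0.371, 0.648, 0.648 and 0.833 in that order. Limma called 0 members of these lists over all targets. With the block and within day A the medians were 0.584 and 0.345 for S100 genes, 0.429 and 0.351 for macrophage markers, 0.383 and 0.203 for cytokines, 0.38 and 0.209 for keratinocyte differentiation. They were 0.206 and 0.191 for glycolysis, 0.157 and 0.0943 for T and NK markers, 0.309 and 0.332 for the cell cycle, 0.177 and 0.172 for the proteasome and 0.277 and 0.151 for fibroblast genes. The fibroblast and T and NK lists were lost within day A. Of the calves in this contrast, day A lacks only calf hay_day70_101, so its medians are those without that calf. Smooth muscle markers had a median of 0.478 (adjusted p = 0.323). BP40 precursor (2.50, adjusted p = 0.0231), MMP-3 (2.96, adjusted p = 0.0401), an MHC class II antigen (1.74, adjusted p = 0.0479) and BOVINE0001S00041059 (2.55, adjusted p = 0.0401) were higher in 3 of 3 calves on grain. These 4 dim targets were the only calls and were chosen after their values were seen. The high affinity immunoglobulin E receptor alpha subunit of mast cells, not counted in its list, lay at 2.13 (adjusted p = 0.238). Very-long-chain acyl-CoA synthetase lay at -1.77 (adjusted p = 0.401), CYP1B1 at -1.90 (adjusted p = 0.419) and CYP1A1 at -2.27 (adjusted p = 0.437, with a dim target at 0.55). An unadjusted p under 0.05 was found for 1862 targets, and 7.55% of all targets had no overlap where chance gives 10%. The count was 0 with the block, 1 within day A that was none of these 4, 1 with the authors' RMA values, 0 without calf grain_day70_107 or grain_day70_112, 1 without calf hay_day70_106 and 6 without calf grain_day70_102.

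From day 56 to day 70 on grain no gene passed. Cholesterol synthesis had a median of 0.201 (adjusted p = 0.0205, with FDFT1, an early enzyme of sterol formation, at 0.47), red blood cell markers 0.321 (adjusted p = 0.0205, with HBB at 0.59) and fibroblast genes -0.128 (adjusted p = 0.0205). An estimated correlation gave adjusted p = 0.877, 0.866 and 0.935, and limma called 0 members in either count. The fibroblast median turned to 0.0229 without calf grain_day56_110, and all 6 calves were of day A. Contactin associated protein-like 2 (1.02), TTC9 (0.64), cytochrome P450 2C41 (-0.69) and neuroserpin (-0.78) had the smallest p (adjusted p = 1). In limma 0 targets were called, 469 had an unadjusted p under 0.05, and 8.32% had no overlap where chance gives 10%.

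From day 56 to day 70 on hay oxidative phosphorylation genes lay lower as a list, with a median of -0.48 (adjusted p = 6.88e-11, 0 called and 18 lower adjusted over the list alone) and NDUFB6, NDUFB10 and NDUFA1 at -0.97, -0.83 and -0.80. Ribosomal proteins had -0.301 (adjusted p = 2.88e-05, with RPLP2 at -0.78 and 2 further targets of it at 0.13 and -0.03) and the proteasome -0.291 (adjusted p = 0.00035, 2 lower adjusted over the list alone, with PSMA7 at -0.74). With an estimated correlation the adjusted p was 0.387, 0.387 and 0.772 in that order. Within days A and B the medians were -0.391 and -0.668 for oxidative phosphorylation, -0.249 and -0.17 for ribosomal proteins and -0.215 and -0.371 for the proteasome, where the proteasome list was lost within day A, and the block could not move the pooled values, with equal numbers of arrays per day. The single call was the dim target BOVINE0001S00046461 (-2.15, SE 0.281, adjusted p = 0.0499), lower in 3 of 3 calves and chosen after its values were seen. The immunoglobulin E receptor alpha subunit (-2.29, adjusted p = 0.226), glutamate receptor 3 (1.99, adjusted p = 0.328) and ARAP3 (0.95, adjusted p = 0.328) did not pass. An unadjusted p under 0.05 was found for 4589 targets and 16.9% of all targets had no overlap where chance gives 10%. The count was 0 with the block, 2 within day A with 0 in common, 2 without calf hay_day56_109 and 0 without calf hay_day56_104 or hay_day56_115. Without calf hay_day70_106 or hay_day70_101 it was 1, a different target that was higher.

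The change from day 56 to day 70 was then compared between the diets. The change on grain minus that on hay had a median of 0.401 for oxidative phosphorylation (adjusted p = 3.95e-09, with NDUFA1 at 0.78 and 2 further targets of it at 0.64 and -0.37), 0.35 for the proteasome (adjusted p = 2.12e-05) and 0.253 for ribosomal proteins (adjusted p = 0.00106). On grain alone these lists had medians of -0.0474, 0.0498 and -0.0366, against the falls on hay given above. Those falls, the diet differences at day 56 and the differences of changes share the hay calves of day 56. The adjusted p with an estimated correlation was 0.576, 0.667 and 0.576. S100 and antimicrobial genes had 0.436 (adjusted p = 0.0104, with S100A8 at 0.84), keratinocyte differentiation 0.229 (adjusted p = 0.0423, with KRT4 at 3.73), macrophage markers 0.261 (adjusted p = 0.0423, with TYROBP at 0.89) and cytokines 0.371 (adjusted p = 0.0432, with CCL20 at 1.45). An estimated correlation gave adjusted p = 0.667 for each. The block could not move the medians, as the 2 groups of each diet had the same days, and within day A they were 0.401, 0.271, 0.195, 0.154, 0.0841, 0.0978 and 0.103 in the order given. The keratinocyte, macrophage and cytokine lists were lost with the block and within day A, and the S100 list within day A. The immunoglobulin E receptor alpha subunit (2.39), G6e (1.65) and ARAP3 (-1.12) had the smallest p among single genes (adjusted p = 1). In limma 0 targets were called, 1115 had an unadjusted p under 0.05, and without calf hay_day70_106 or hay_day70_101 1 target was called.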

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

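The 3 patterns weighed here were picked after the results were seen; the muscle and processing day tests of calf milk_day42_114 and, for the hay and grain counts, the processing day test and the ratio with day 42 calves kept apart were chosen only after the result was seen.

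Smooth muscle markers stood high in calf milk_day42_114 and in the 3 day 14 calves, at 13.14 to 13.59 against 10.11 to 10.85 in all others. In this calf 11 of 12 markers were over 1 log2 unit above the mean of the other day 42 calves, CNN1 by 5.32 and DES by 4.77. Muscle tissue in the sample was left open, since of the lists of other tissue below the epithelium fibroblast genes lay 1.05 higher in median, but endothelial genes only 0.396 and nerve genes 0.233. The processing day was excluded for calf milk_day42_114, since its smaller gap to the hay arrays of the same day was 3.08. A wrong age label was left open. The log2 difference of fetal minus adult beta globin was 1.5 in this calf, but the measure did not follow age, at 0.231 to 1.78 in day 14 calves and 0.515 to 3.63 in weaned calves, so the test decided nothing. Over all targets its array correlated best with a day 14 array. On principal component 1 it lay at 106.4, beside calf milk_day14_108 at 104.6, of the same processing day. That likeness includes the muscle markers, so it cannot decide the label of calf milk_day42_114. Without this calf 609 targets passed for age on milk, 562 of them lower, where none did with it.

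More targets passed against day 42 on hay than on grain, 4040 against 1571. A generally smaller response to grain at day 56 was left open. The ratio of the grain to the hay change stated beforehand (0.89) shares its day 42 calves between both changes. Its bound of 0.8 was also too strict, since any ratio below 1 is a smaller response. With each day 42 calf in turn kept out of the choice of targets and used for the changes, the ratio was 0.883, 0.899 and 0.876, and 0.841 to 0.938 when 1 calf of day 56 was left out as well. This separated only the choice of targets. The calf kept out still served both the grain and the hay change, and the ratios share their day 56 calves. The processing day was left open, as the ratio of the counts was 2.73 with the day as a block but 1.44 within day A, which holds fewer hay than grain calves. With array weights, a run that did not converge, the counts were 10471 on grain and 10391 on hay. With gene-by-gene weights they were 9257 and 9226, so the excess on hay was absent in both. Those weights were 2.95, 1.36 and 1.61 for the grain calves of day 56, and 0.832, 0.753 and 1.9 for the hay calves. The diets were thus weighted unequally, and these counts cannot decide whether hay had more. The counts moved with single calves, from 378 to 1936 on grain and from 1585 to 3831 on hay. These extremes came from leaving out a day 42 calf, which both counts share. Without calf milk_day42_117 hay had 1585 and grain 378, and without calf milk_day42_103 hay had 3831 and grain 1936. Without calf milk_day42_114 they were 3038 and 824, so hay kept more in each of these runs. The difference in number may still be smaller or larger in other calves.

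CYP1A1 and CYP1B1 lay lower on grain than on hay, at -1.95 and -1.63 over both ages, although neither passed the threshold over all targets. No single calf carried the differences, since at least 88.6% of each was kept without any 1 weaned calf. Both genes were picked for a small p over these same calves. That made this outcome likely beforehand, so it is no independent test. The processing day was excluded, with 94.8% kept as a block. Muscle in the sample was left open, although 100.5% was kept beside the muscle covariate. The weaned calves spanned only 10.11 to 10.85 in the muscle score, and its slope rested mainly on calf milk_day42_114. The covariate could therefore hardly have shrunk these differences. A dietary ligand of the receptor that controls both genes may differ between hay and starter grain, which was not tested here. Over the alternatives the adjusted p ranged from 0.0103 to 0.37 for CYP1A1 and from 0.00425 to 0.332 for CYP1B1.

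The remaining lists and the target below differed between diets or in their change with age. Oxidative phosphorylation genes lay lower on grain at day 56 (median -0.323) and their change to day 70 on grain minus that on hay was 0.401, with -0.0474 on grain and -0.48 on hay. Ribosomal proteins gave -0.202 and 0.253 in these contrasts, and the proteasome -0.142 and 0.35. The difference at day 56, the change on hay and the difference of changes all use the same hay calves of day 56. They are therefore not separate results. Cell cycle genes lay higher on grain at day 56 (0.224), as did fibroblast genes (0.154), and oxidative stress genes lay lower (-0.0972). The cell cycle median turned negative without calf hay_day56_115. The fibroblast, oxidative stress and proteasome lists of day 56 were lost within day A. In the same difference of changes S100 genes gave 0.436, cytokines 0.371, macrophage markers 0.261 and keratinocyte differentiation 0.229, lists that were lost within day A. The unnamed target BOVINE0001S00046461 lay lower on grain at day 56 (-2.52). Each of these list results was lost with an estimated correlation, where the adjusted p was 0.361 to 0.791. With groups of 3, no test for a sample far from the others was made.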

How the results depend on the processing

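With 3 calves per group, counts of targets past the threshold depended on single calves, and the limit of detection was the background of the arrays. Targets near it, below the median mean of 9.318, are least certain. No paired analysis was possible because each calf gave 1 sample and no replicate number occurs in more than 1 group. The series table was named beforehand as an alternative and was not run, since it is identical to the RMA values. Below, counts are targets past the threshold, and except where stated the cause of a changed or reversed value was not tested.

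With the authors' RMA values the count was 1 for diet at day 70 and 0 for age on hay. Without background correction it was 0 for diet at both ages, diet at day 70 and age on hay, and with normexp at offset 0 it was 0 for age on hay. Median scaling gave 7 for diet at both ages and 2 for age on hay, and shifted the median of all targets of a group by up to 0.108. Leaving out dim targets gave 0 for diet at both ages, diet at days 56 and 70 and age on hay, by construction, since those calls were dim. With only the groups compared in the fit the count was 2003 for hay at day 56, 13 for diet at both ages, 0 for diet at day 56, 2 for diet at day 70 and 0 for age on hay.

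Array weights gave 3258 for age on milk, 10547 for weaning, 10471 for grain, 10391 for hay, 678 for diet at both ages, 2 for diet at day 56, 374 for diet at day 70 and 3154 for age on grain. That run warned of missing convergence and weighted calf grain_day70_107 at 787. A gene-by-gene method was therefore chosen after the first was seen and weighted that calf at 11. Its counts were 0 for age on milk, 9052 for weaning, 9257 for grain and 9226 for hay. They were 336 for diet at both ages, 2 for diet at day 56, 92 for diet at day 70 and 348 for age on grain.

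With the processing day as a block the count was 11 for age on milk, 0 for diet at both ages, 0 for diet at day 70 and 0 for age on hay. Within day A it was 525 for age on milk, 2740 for weaning, 1824 for hay, 2 for diet at day 56, 1 for diet at day 70 and 2 for age on hay. There the smooth muscle median on grain was 0.127 and the fibroblast median 0.398. Of the calves in the grain contrast, only calf milk_day42_114 lies outside day A, so these are the medians without that calf. With the smooth muscle mean as a covariate the count was 2457 for weaning, 1027 for grain, 0 for diet at both ages, 2 for diet at day 70 and 0 for age on hay. The smooth muscle median for age on milk was then -0.0939 with the test pointing up, which follows from the covariate, and the fibroblast median was 0.191 for age on milk and 0.373 on grain. The oxidative stress median of diet at both ages was 0.0144.

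Of 78 list results with the preset correlation 0 held with an estimated one, and fry passed 28, of which 26 were among the 78 and 2 were not. Fry asks whether a list moved on balance and not whether it moved more than other genes. The other target of monoamine oxidase B lay at -0.62 for weaning and -0.89 on grain.

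Leaving out 1 calf gave counts from 1295 to 4473 for weaning, with 2179 without calf milk_day42_114. On grain they ran from 378 to 1936, with 444, 648 and 689 without calves grain_day56_105, grain_day56_110 and grain_day56_116 and 824 without calf milk_day42_114. On hay they ran from 1585 to 3831, with 1706 and 2404 without calves hay_day56_109 and hay_day56_115. For age on milk they ran from 0 to 609, with 7 and 5 without calves milk_day14_113 and milk_day14_108. For diet at both ages they ran from 0 to 15, with 10 without calf grain_day56_105. They were 0 to 2 for diet at day 56, 0 to 6 for diet at day 70, 0 for age on grain, 0 to 2 for age on hay and 0 to 1 for the interaction. Reversed medians, with the opposite extreme, were 0.0229 for fibroblast genes in age on grain without calf grain_day56_110 (-0.248 without grain_day56_116) and -0.106 for the cell cycle in diet at day 56 without calf hay_day56_115 (0.438 without grain_day56_110). For the gene list interferon response, age on milk, the median was 0.12 without calf milk_day14_118 and -0.925 without calf milk_day14_108. Without calf milk_day42_114 the grain medians were 0.127 for smooth muscle and 0.398 for fibroblast genes, against -1.59 and -0.129 without calf milk_day42_103. Without calf grain_day70_107 the oxidative stress median of diet at both ages was 0.0185.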

Other observations

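The exchange of diets within each age was a test chosen only after the result was seen, and the targets in the next paragraph were picked after their values were seen.

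MMP-3, a protease that opens the extracellular matrix, had higher values on grain at both ages, but passed the threshold only at day 70 and over both ages. Its log2 intensity was 9.82, 11.53 and 9.77 in the grain calves of day 70, 8.23, 8.70 and 8.75 in those of day 56, and between 6.52 and 7.93 in all others. Calf grain_day70_107, which had the highest MMP-3, also had the highest BP40 precursor (10.62). The unnamed target BOVINE0001S00046461 lay at 8.87, 8.98 and 9.86 in the hay calves of day 56 and between 6.15 and 7.72 in all 15 others.

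The calves were also regrouped, and the targets past the threshold counted again. For weaning the fit had 1 mean each for the weaned, the day 42 and the day 14 calves. In it 1 of 100 groupings, the real one with 4263, reached its count, and the highest other had 1921. For diet at both ages, in a fit of diet and age, the real grouping had 0, which every grouping reaches (100 of 100, with 2 in the highest), so this decided nothing. When diets were exchanged within each age, in the fit used for the report, 1 of 100 reached the real count of 4 and the highest other had 2. The interaction had 0, reached by 100 of 100 with 2 in the highest, so this also decided nothing.

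With 3 against 3 calves there were 10 groupings, too few for a share under 0.05. On grain 1 of 10 reached the real 1571 (highest other 0), on hay 1 of 10 reached 4040 (highest other 1), and for diet at day 70 1 of 10 reached 4 (highest other 1). For diet at day 56 2 of 10 reached 1, which was also the highest other, for age on hay 3 of 10 reached 1 (highest other 5), and for age on grain 10 of 10 reached 0 (highest other 1). For age on milk 10 of 10 reached 0, and a grouping that set calves milk_day42_103, milk_day14_118 and milk_day14_113 against the other 3 had 2531. The other 3 include both milk arrays of processing day B, so that grouping partly follows the processing day.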
